A study of Mus musculus with 6 samples.

How the data were processed

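RNA from 6 samples of mouse leukemia cells was measured on Illumina bead arrays, 1 array per sample. Per the labels, T cell acute lymphoblastic leukemia had been induced with NOTCH1, and double-positive cells (CD4 and CD8) that also carried GFP were sorted from bone marrow 4 weeks after transplantation. The labels form 2 groups of 3 arrays, control and Klf4-deficient, and give the sex as male throughout. Total RNA was labelled with biotin, and a service company carried out hybridisation, scanning and image analysis. The labels do not state that the 3 samples of a group come from separate animals, so the p-values then measure only the spread between samples, which may be technical.

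The deposited values are probe intensity on a linear scale, made in BeadStudio per the submitters' processing notes, with no version given. The deposited values run below 0 for 31.3% to 34.2% of the probes of an array, which goes with subtraction of a background. The method of that subtraction, any normalization between arrays, detection p-values and the genome build are not given in the sources used here.

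Values under 0 were set to 0, 16 was added, and the log2 values were quantile normalized. Of 45281 probes, 34885 carried 1 gene symbol in the platform's probe annotation, 18 carried several and 10378 were unnamed here. The last 2 kinds were left out of the gene tests. For each of the 19057 genes the probe with the highest mean over all arrays was used, which was a choice among several probes for 9172 genes. A table of RefSeq genes on the mouse assembly GRCm38.p6 served only to look up gene names and the order of neighbouring genes. No probe carried the name Map2k7, so Map2k7 was not analysed here.

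A probe was taken as above background on an array when its signal passed 3 times the SD of the background, estimated by mirroring the negative values around 0. The limit lay between 21.8 and 23.7 and was defined after the data were seen. No fold is given for a gene under the limit in both groups. The number of arrays limits the precision of every value.

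Differences are Klf4-deficient minus control on the log2 scale, from limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with Benjamini-Hochberg adjustment over the 19057 genes and a threshold of 0.05. The same threshold holds for every other test. Errors given with a log2 difference are standard errors (SE), and those given with a signal are SDs over 3 arrays. An exact two-sided permutation test of 3 against 3 arrays cannot go below p = 0.10, so none was used on single genes.

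Gene lists were fixed before the data were examined. They covered the JNK cascade, other MAP kinases, MAP kinase phosphatases, AP-1 and immediate early genes, the Klf and Sp family, Notch, CDK inhibitors, G1/S and G2/M genes, and anti-apoptotic and pro-apoptotic genes. Others held p53 targets, Myc targets, double-positive thymocyte genes, T cell receptor signalling, mature T cell genes, T-ALL oncogenes, interferon-stimulated genes, NF-kappaB, JAK-STAT, chemokine receptors and PI3K. Glycolysis, oxidative phosphorylation, cholesterol synthesis, the unfolded protein response, heat shock, hypoxia and histone genes made up the rest of the pathways. Markers of erythroid, neutrophil, monocyte, B, NK, megakaryocyte and stromal cells stood for other cells of the bone marrow, and a list of sex-specific transcripts served as a check of the labels. The arrays measured between 75.9% and 100% of the genes of the 36 tested lists.

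Each list was tested with camera from limma, with a preset correlation between genes of 0.01, and adjusted over the 36 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it. Within a list, single genes were also adjusted over the list alone. Reactome pathways of 15 to 300 measured genes came from the mouse collection in fgsea 1.28.0 and were tested in the same way. The background of both was the 19057 genes.

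The genes named here follow a rule fixed before the data were examined. Klf4, Map2k7, Mapk8, Mapk9 and Jun were always named. Up to 15 genes per direction with the largest differences were named among those past the threshold whose groups did not overlap. Where fewer than 10 passed in a direction, genes with the smallest p filled the number up to 10, stated as not having passed. Up to 4 members with the smallest unadjusted p were named per list. Any other gene is marked as chosen after its values were seen.

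The alternatives tried were centring arrays on their median, cyclic loess, offsets of 1 and 50, the brighter probes, no variance trend, robust moderation, array weights, the replicate number as a block, the mean of a gene's probes, every probe, other thresholds, camera on ranks, and leaving out each array in turn. Alternatives added after the data were seen were no normalization between arrays, normalization before the floor, the first Klf4-deficient array alone against the controls, a score of other cells' markers as a covariate, and genes above background alone. The last kept genes above background in all 3 arrays of either group. A group difference can itself decide that filter, so a larger list median under it is no separate support. The method was tested on simulated data with the variances of these arrays. Of 67 genes changed 1.5-fold, 18 were recovered (26.9%), against 40 of 67 changed 2-fold and 58 of 66 changed 4-fold. The changed genes were drawn from those above background on all 6 arrays, so these shares do not hold for dimmer genes. Beside the 200 changed genes, 3 unchanged ones were called. In simulated arrays with no change, limma called 0 genes and camera called 0 lists. Since the simulated genes were not correlated, this cannot show how often camera calls a list of correlated genes without a change. A shift of 0.3 added to the interferon list was estimated as 0.27 and called. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.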

Results

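Gene expression was compared between 3 control arrays and 3 arrays labelled Klf4-deficient, each from sorted double-positive T-ALL cells of mouse bone marrow. Klf4 encodes a zinc finger transcription factor that restrains proliferation in several cell types, and the study's title names the Map2k7 and Jnk pathway. The mean probe signal was 442, 417 and 445 in control arrays 1, 2 and 3 and 426, 432 and 359 in Klf4-deficient arrays 1, 2 and 3. Between 17152 and 17446 of the 45281 probes (37.9% to 38.5%) were above background on an array. Correlations between arrays, taken across probes, ranged from 0.983 to 0.993, and probes are not independent replicates. The first principal component held 39.1% of the variance and placed Klf4-deficient array 3 apart from the others.

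The Klf4 probe in use gave more signal in the arrays labelled Klf4-deficient than in the controls. Its signal was 44, 18.4 and 24.6 in the control arrays and 80.6, 46 and 85.4 in the Klf4-deficient arrays. The means were 29.0 ± 13.4 (SD, n = 3) and 70.7 ± 21.5 (SD, n = 3). It was above background on 2 of 3 control arrays and on 3 of 3 Klf4-deficient arrays. The log2 difference of Klf4 was 1.03 ± 0.32 (SE) and did not pass, with an adjusted p of 0.567 from limma. Both other Klf4 probes were under the background limit on every array. The position of the probes relative to the deleted part of the gene is unknown, so this measurement may check nothing about the deletion.

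**Figure D1:**
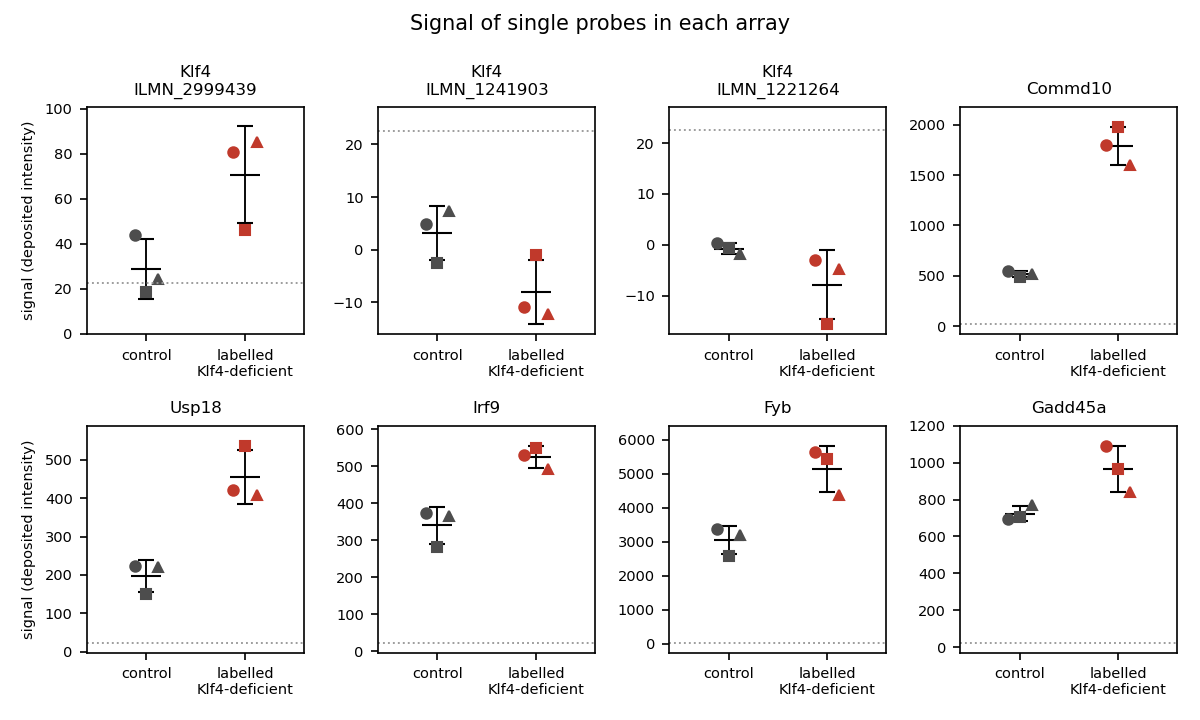
Signal of the Klf4 and Commd10 probes in use on each array (deposited intensity), by group, with 3 arrays per group. Commd10 lay between 489 and 548 in controls and between 1601 and 1972 in Klf4-deficient arrays, while Klf4 lay between 18.4 and 44 and between 46 and 85.4.

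Commd10 was the single gene above background that passed when adjusted over all genes. Commd10 belongs to the COMM domain family of proteins, which take part in endosomal sorting and in the control of NF-kappaB. Its mean signal was 520 in controls and 1789 in the arrays labelled Klf4-deficient. On the normalized log2 scale Commd10 rose by 1.85 ± 0.03 (SE, adjusted p = 0.0016 from limma), which is 3.61-fold. This fold comes from the normalized values and is not the ratio of the mean signals. A second Commd10 probe was under the background limit on all 6 arrays. Neighbours on chromosome 18 were taken only from genes above background in all 3 arrays of a group. The 10 nearest of these on both sides of Commd10 had a median log2 difference of 0.06, from -0.10 to 0.28, and 0 passed in limma at the adjusted threshold. Tspyl5 also passed (adjusted p = 0.0491) but lay under the background limit on every array, so no fold is given. Its call was lost in 14 of 19 alternatives, among them leaving out any control array.

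In limma, 2 genes were higher and 0 were lower at the adjusted threshold, while 1451 genes had an unadjusted p under 0.05, of which 663 were higher and 788 lower. Chance alone would give 953. Over all 19057 genes 2205 (11.6%) had groups that did not overlap, where chance gives 10%. Among the 8866 genes above background in all 3 arrays of a group, a filter that a group difference can itself decide, the number was 1607 (18.1%). Of these, 710 were higher and 897 lower. Leaving out control array 1, 2 or 3 gave 6, 3 and 10 called genes, with 5, 2 and 9 of them lower. Leaving out Klf4-deficient array 1, 2 or 3 gave 21, 13 and 21, with 20, 13 and 21 of them higher, and Commd10 was called in each of the 6 cases. Adcy8 and Tmc7, called without Klf4-deficient array 1, and Tspyl5, called without array 2 or 3, were under the background limit on every array. The limit was not applied to the other calls, so these counts are not read as numbers of changed genes. With no normalization between arrays 2 genes were higher and 1 lower, Commd10 was not among them (1.75, adjusted p = 0.0545), and the median of the genes above background moved to -0.11. The adjusted p of Commd10 was 0.687 with the replicate number as a block and 0.104 with the mean of its probes (log2 1.18).

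Other genes named by the rule did not pass in limma and are given as values. Fyb, an adaptor of T cell receptor and integrin signalling, had a mean signal of 3056 in controls and 5149 in Klf4-deficient arrays (log2 0.85 ± 0.08 SE, adjusted p = 0.243). Fyb passed when genes above background alone were tested (adjusted p = 0.0319) and with the brighter probes alone (adjusted p = 0.0258), and its second probe differed by 0.66 ± 0.16. Hsp90b1, a chaperone of the endoplasmic reticulum, differed by 0.32 ± 0.04, and Dusp5, a nuclear phosphatase of ERK, by 0.35 ± 0.04 (adjusted p = 0.327 for both). Msmo1, an enzyme of cholesterol synthesis, differed by 0.32 ± 0.03 (adjusted p = 0.164), and Bahd1, a protein of heterochromatin, by 0.28 ± 0.02 (adjusted p = 0.155). In the other direction, the mismatch repair gene Mlh3 differed by -0.40 ± 0.02 and the centrosomal gene Sfi1 by -0.30 ± 0.02 (adjusted p = 0.125 for both). Vmac differed by -0.29 ± 0.03 and Lgals4, a galectin, by -0.17 ± 0.02 (adjusted p = 0.243 for both). Tmc7, Adcy8 and Zxdb on the higher side and Gm10044, Ackr2, Sema3a, Gchfr, Baz1b and Cfc1 on the lower side were under the background limit in both groups.

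Transcripts of the JNK cascade, the stress kinase pathway named in the title, showed no shift between the groups that passed a test. The 33 measured members had a median log2 difference of 0.04 (20 above 0, 13 below 0), with an adjusted p of 0.402 from camera and 0.731 with an estimated correlation. Mapk8 and Mapk9, which encode the JNK1 and JNK2 kinases, differed by 0.03 ± 0.05 (SE) and -0.18 ± 0.08. Jun, a transcription factor that JNK phosphorylates, differed by 0.36 ± 0.30, and the adjusted p values of the 3 genes in limma were 0.931, 0.742 and 0.775. Gadd45a, a stress-induced gene upstream of the MAP kinases and a p53 target, rose by 0.51 ± 0.07 when adjusted over the list alone (adjusted p = 0.0393), and had an adjusted p of 0.346 over all genes. Gadd45b differed by 0.39 ± 0.17 and did not pass. The median of the list was -0.04 with arrays centred on the median, -0.06 with no normalization, and -0.04 without Klf4-deficient array 3. Transcript levels do not measure kinase activity, and Map2k7 was not analysed here.

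The fixed list of interferon-stimulated genes, which type I interferon induces against viruses, rose in the arrays labelled Klf4-deficient. The 43 measured genes had a median log2 difference of 0.34, and 22 of them had groups that did not overlap with the Klf4-deficient arrays higher and 0 with them lower, where chance gives 10%. The adjusted p was 1.39e-09 from camera and 0.353 with an estimated correlation. Usp18, the protease that removes ISG15 from proteins, rose by 1.24 ± 0.15 (SE), and Irf9, the DNA-binding part of the interferon-activated STAT complex, rose by 0.72 ± 0.09. Both had an adjusted p of 0.0119 when adjusted over the list alone, and 0 of the 43 passed over all genes in limma, against 20 higher and 0 lower at an unadjusted p under 0.05. Ifi35 differed by 0.38 ± 0.08 and did not pass, and Mx2, a GTPase that acts against viruses, was above background on 1 of 3 control arrays and 3 of 3 Klf4-deficient arrays. Relative to the control mean, the list lay at 0.21, 0.36 and 0.42 in Klf4-deficient arrays 1, 2 and 3 and between -0.04 and 0.03 in the controls. Reactome's interferon pathways did not pass in camera, with medians of -0.04 for Interferon alpha beta signaling (26 genes, adjusted p = 0.938), 0.04 for Interferon gamma signaling (95 genes, adjusted p = 0.129), 0.06 for ISG15 antiviral mechanism (22 genes, adjusted p = 0.450) and 0.03 for Interferon Signaling (136 genes, adjusted p = 0.394). In the same 3 arrays the erythroid markers lay at 0.18, 1.07 and 1.75 and the monocyte markers at 0.07, 0.71 and 1.34.

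**Figure D2:**
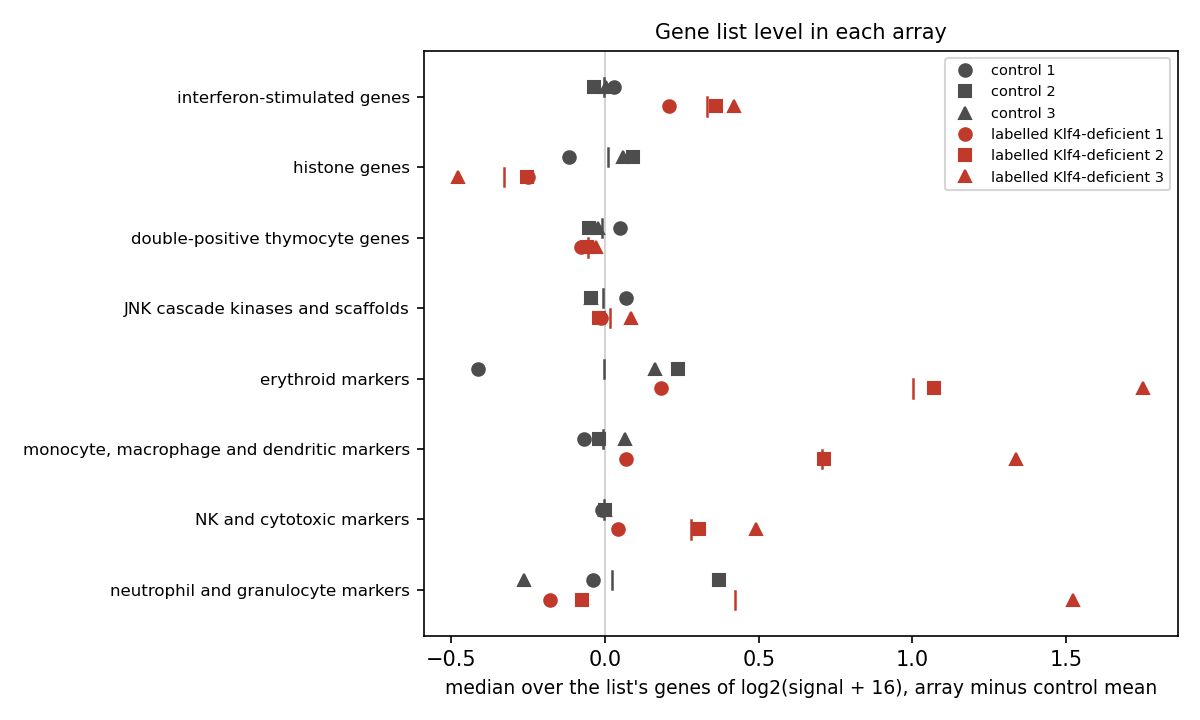
Median over the genes of each list of log2(signal + 16), array minus control mean, for the 6 arrays, with vertical bars at the group means. Interferon-stimulated genes lay between 0.21 and 0.42 in the Klf4-deficient arrays, and erythroid and monocyte markers were highest in Klf4-deficient arrays 2 and 3.

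Histone genes, whose products package newly made DNA, fell in the arrays labelled Klf4-deficient. The 30 measured genes had a median log2 difference of -0.30, with 26 of them below 0 (adjusted p = 1.94e-08 from camera, adjusted p = 0.391 with an estimated correlation). H4c3 fell by 0.55 ± 0.08 (SE), H1f5 by 0.67 ± 0.13, H2bc11 by 0.41 ± 0.08 and H4c8 by 0.39 ± 0.08, the 4 genes that passed when adjusted over the list alone (adjusted p between 0.0334 and 0.0404). Over 21 alternatives the difference of H4c8 ran from -0.50 to -0.05. Over all genes 0 passed in limma, and 13 were lower at an unadjusted p under 0.05. The histone median was -0.20 with the mean of a gene's probes, with the call kept. The list lay at -0.25, -0.26 and -0.48 in Klf4-deficient arrays 1, 2 and 3 and at -0.12, 0.09 and 0.06 in the controls, while erythroid and monocyte markers were highest in Klf4-deficient arrays 2 and 3, at 1.07 and 1.75 and at 0.71 and 1.34. The G1/S and DNA replication genes, which are active in the same part of the cell cycle, had a median of -0.05 (adjusted p = 0.738), and the G2/M and mitosis genes one of -0.01 (adjusted p = 0.80), both from camera. Among single arrays the G1/S list lay at -0.20 in control array 1, at -0.26 in Klf4-deficient array 3, and between -0.01 and 0.12 in the others. The G1/S list passed as lower without control array 1 (-0.13, adjusted p = 0.0246) and without Klf4-deficient array 1 (-0.14, adjusted p = 0.0424). With the score of other cells' markers as a covariate it passed as higher (0.08, adjusted p = 0.0430), as did the G2/M list (0.17, adjusted p = 0.0395).

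Most Reactome pathways that were lower held histone genes. Of 691 pathways, camera called 30 lower and 0 higher, and 29 of the 30 held at least 1 gene of the histone list. DNA methylation had a median log2 difference of -0.34 (adjusted p = 1.78e-08), Meiotic recombination one of -0.31 (adjusted p = 1.81e-10) and Packaging Of Telomere Ends one of -0.37 (adjusted p = 1.79e-07). These pathways, chosen after their values were seen, share core histones. The exception was Intraflagellar transport, at -0.11 (adjusted p = 0.0105). Without the histone list's genes, 14 of 689 pathways were lower and 0 higher. With an estimated correlation the lowest adjusted p was 0.998, so 0 of the 30 calls held. Leaving out control array 1, 2 or 3 gave 4, 1 and 0 higher pathways with 41, 24 and 21 lower. Leaving out Klf4-deficient array 1, 2 or 3 gave 6, 1 and 50 higher with 41, 33 and 19 lower. Arrays centred on the median gave 8 higher and 51 lower, and no normalization 8 higher and 46 lower.

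Erythroid, monocyte and NK markers were higher in Klf4-deficient arrays 2 and 3 than in any control, although the cells had been sorted for GFP, CD4 and CD8. Erythroid markers rose with a median of 0.91 over 19 genes (adjusted p = 6.63e-07 from camera, adjusted p = 0.394 with an estimated correlation). Tfrc, the transferrin receptor, rose by 0.53 ± 0.08 (SE) when adjusted over the list alone (adjusted p = 0.0350). The signal of Hba-a1, an alpha globin, was near the top of the scale on every array, from 31501 to 39931, so its difference is not read. Monocyte, macrophage and dendritic markers rose with a median of 0.78 over 26 genes (adjusted p = 2.50e-08, adjusted p = 0.419 with an estimated correlation). Mrc1, the macrophage mannose receptor, differed by 0.94 ± 0.27, and C1qc, a part of complement C1, by 1.01 ± 0.32. NK and cytotoxic markers rose with a median of 0.33 over 21 genes (adjusted p = 8.86e-04, adjusted p = 0.374 with an estimated correlation), and lay at 0.04, 0.30 and 0.49 in Klf4-deficient arrays 1, 2 and 3. Ctsw, a protease of cytotoxic cells, differed by 0.91 ± 0.24, and the chemokine Ccl5 by 1.36 ± 0.38. The erythroid median was 0.59 without Klf4-deficient array 3 and 1.41 without Klf4-deficient array 1, and the monocyte median 0.47 without Klf4-deficient array 3, with the calls kept, and the erythroid median was 1.5 with an offset of 1. The NK call was lost without Klf4-deficient array 3 (0.20, adjusted p = 0.0874). With 10 of the 21 NK markers above background, the NK median was 0.84 with genes above background alone, 0.77 with the brighter probes, 0.78 with an offset of 1 and 0.13 with an offset of 50, the call kept in each. The first of these values is not read as support, since the filter can admit genes through the Klf4-deficient group alone. Klrd1 entered in this way, above background on 0 of 3 control arrays and 3 of 3 Klf4-deficient arrays. Neutrophil markers had a median of 0.39 (adjusted p = 0.0932), with Klf4-deficient array 3 at 1.52 and the other Klf4-deficient arrays at -0.18 and -0.08. The neutrophil list passed without control array 2 (0.64, adjusted p = 0.0216), Klf4-deficient array 1 (0.69, adjusted p = 0.0099) and Klf4-deficient array 2 (0.64, adjusted p = 0.0147), and the megakaryocyte list without control array 1 (0.14, adjusted p = 0.0402) and Klf4-deficient array 1 (0.19, adjusted p = 0.0490). Both lists also passed with no normalization (adjusted p = 0.0329 and 0.0177) and with the brighter probes (adjusted p = 0.0205 and 0.0307), the neutrophil list with genes above background alone (adjusted p = 0.0210) and camera on ranks (adjusted p = 0.0337), and the megakaryocyte list with arrays centred on the median (adjusted p = 0.0114), array weights (adjusted p = 0.0393) and the mean of a gene's probes (adjusted p = 0.0458). Megakaryocyte markers had a median of 0.21 (adjusted p = 0.0895), B lineage markers one of 0.09 and stromal markers one of -0.02 (adjusted p = 0.338 for both), and Klf4-deficient array 2 lay at -0.08 for each of the last 2 lists.

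Heat shock genes and genes of the unfolded protein and integrated stress response rose in the arrays labelled Klf4-deficient. Heat shock genes had a median log2 difference of 0.19 over 18 genes (adjusted p = 8.86e-04 from camera, adjusted p = 0.374 with an estimated correlation). In Klf4-deficient arrays 1, 2 and 3 the heat shock list lay at 0.25, 0.07 and 0.19. In the controls it lay at 0.08, -0.04 and 0.002, so single arrays of the groups overlapped. The mitochondrial chaperonin Hspe1 differed by 0.25 ± 0.05 (SE), Hsp90aa1 by 0.29 ± 0.08 and Dnajb1 by 0.19 ± 0.06, none past its test. With arrays centred on the median the heat shock call was lost (0.12, adjusted p = 0.0632), and with no normalization the median was 0.09 with the call kept. Related Reactome pathways did not pass in camera, with medians of 0.03 for Protein folding (adjusted p = 0.734), 0.06 for Chaperonin-mediated protein folding (adjusted p = 0.699) and 0.04 for HSF1-dependent transactivation (adjusted p = 0.891). Unfolded protein and integrated stress response genes had a median of 0.14 over 28 genes (adjusted p = 0.0266, adjusted p = 0.353 with an estimated correlation). Hsp90b1 rose by 0.32 ± 0.04 and Creld2, a chaperone of the endoplasmic reticulum, by 0.21 ± 0.03, both with an adjusted p of 0.00816 when adjusted over the list alone. Slc7a11, the cystine transporter induced by Atf4, differed by -0.68 ± 0.15 and Ddit3, which encodes the stress factor CHOP, by 0.14 ± 0.03. The unfolded protein call was lost with arrays centred on the median (0.10, adjusted p = 0.192), with no normalization (0.07, adjusted p = 0.118), with genes above background alone (0.09, adjusted p = 0.194), with camera on ranks (adjusted p = 0.0737), and without control array 2 (0.15, adjusted p = 0.0669), control array 3 (0.10, adjusted p = 0.0683) and Klf4-deficient array 1 (0.10, adjusted p = 0.116). It was kept at 0.08 with an offset of 50. Erythroid and monocyte markers lay at 1.07 and 0.71 in Klf4-deficient array 2 and at 1.75 and 1.34 in array 3.

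Of the signalling lists, NF-kappaB genes and MAP kinase phosphatases rose. NF-kappaB genes had a median log2 difference of 0.14 over 26 genes (adjusted p = 0.0159 from camera, adjusted p = 0.353 with an estimated correlation), and fry gave an adjusted p of 0.0458, its single call among the 36 lists. The inflammatory chemokine Ccl3 differed by 1.47 ± 0.36 (SE), the nuclear NF-kappaB regulator Nfkbiz by 0.38 ± 0.11 and the kinase subunit Ikbkg by -0.30 ± 0.06, none past its test. The NF-kappaB call was lost without Klf4-deficient array 3 (0.11, adjusted p = 0.0833) and with arrays centred on the median (0.10, adjusted p = 0.0656), and kept at 0.08 with no normalization. MAP kinase phosphatases and feedback genes had a median of 0.12 over 19 genes (adjusted p = 0.0347, adjusted p = 0.374 with an estimated correlation). Dusp5 rose by 0.35 ± 0.04 when adjusted over the list alone (adjusted p = 0.00806), Dusp6, an ERK phosphatase, differed by 0.43 ± 0.13 and Dusp22, a phosphatase of T cell signalling, by -0.53 ± 0.15. Over 21 alternatives the difference of Dusp22 ran from -0.66 to -0.02. The phosphatase call was lost with arrays centred on the median (0.04, adjusted p = 0.265), with no normalization (0.02, adjusted p = 0.20), with an offset of 1 (0.06, adjusted p = 0.0538), with the brighter probes (0.13, adjusted p = 0.0649), with camera on ranks (adjusted p = 0.0737), and without control array 1 (0.07, adjusted p = 0.0763), control array 2 (0.10, adjusted p = 0.158), Klf4-deficient array 1 (0.08, adjusted p = 0.0566) and Klf4-deficient array 2 (0.04, adjusted p = 0.0758). It was kept at 0.08 with array weights and with an offset of 50, and at 0.07 with the mean of a gene's probes. Markers of monocytes, which can make Ccl3, lay at 0.07, 0.71 and 1.34 in Klf4-deficient arrays 1, 2 and 3, and erythroid markers at 0.18, 1.07 and 1.75.

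Lists of T cell identity and growth moved in both directions in camera, but in each list single arrays of the 2 groups overlapped. Double-positive thymocyte genes, the program of the developing T cell stage that was sorted, fell with a median log2 difference of -0.06 over 27 genes (adjusted p = 0.0274 from camera, adjusted p = 0.360 with an estimated correlation). This list lay at 0.05, -0.05 and -0.02 in control arrays 1, 2 and 3 and at -0.08, -0.06 and -0.03 in the Klf4-deficient arrays. Cd1d1, which presents lipids, differed by -0.16 ± 0.04 (SE), the E protein gene Tcf3 by -0.37 ± 0.13 and the recombinase gene Rag2 by -0.22 ± 0.11, none past its test. T-ALL oncogenes and early progenitor genes rose with a median of 0.19 over 32 genes (adjusted p = 0.0254, adjusted p = 0.353 with an estimated correlation). The oncogene list lay at -0.02, 0.10 and -0.02 in control arrays 1, 2 and 3 and at 0.04, 0.13 and 0.28 in the Klf4-deficient arrays. Nkx2-1 passed when adjusted over the list alone (adjusted p = 0.0370) but lay under the background limit in both groups, as did Erg, and the Polycomb gene Bmi1 differed by -0.26 ± 0.10. Myc targets and ribosome biogenesis genes rose with a median of 0.06 over 38 genes (adjusted p = 0.0254, adjusted p = 0.540 with an estimated correlation), and this median was -0.02 with no normalization and 0.00 with arrays centred on the median (adjusted p = 0.379), where the call was lost, as it was with the mean of a gene's probes (0.04, adjusted p = 0.0671). In Klf4-deficient arrays 1, 2 and 3 the Myc list lay at 0.163, 0.004 and -0.008, and in the controls at -0.018, -0.021 and 0.006. Nop2 and Ppan, factors of ribosome assembly, differed by 0.22 ± 0.05 and 0.22 ± 0.07, and Tert, the telomerase gene, by -0.42 ± 0.10. The double-positive median was -0.12 without control array 2 and also without Klf4-deficient array 2, -0.15 with arrays centred on the median, -0.17 with no normalization and -0.10 with genes above background alone, with the call kept in each. The double-positive call was lost with the mean of a gene's probes (-0.06, adjusted p = 0.0892), with the brighter probes (-0.08, adjusted p = 0.0608), and without control array 1 (-0.09, adjusted p = 0.102), control array 3 (-0.07, adjusted p = 0.0599) and Klf4-deficient array 1 (-0.05, adjusted p = 0.138), and the Myc call without control array 2 (0.05, adjusted p = 0.0723) and Klf4-deficient array 1 (-0.01, adjusted p = 0.662). The oncogene call was lost without control array 1 (0.15, adjusted p = 0.0786), control array 3 (0.16, adjusted p = 0.0810), Klf4-deficient array 2 (0.22, adjusted p = 0.0543) and Klf4-deficient array 3 (0.14, adjusted p = 0.0880). With 18 of the 32 oncogene list members above background, that median was 0.34 with an offset of 1, 0.08 with an offset of 50, 0.11 with no normalization, 0.10 with the mean of a gene's probes and 0.30 with genes above background alone, the call kept in each. Erythroid and monocyte markers were highest in Klf4-deficient arrays 2 and 3, at 1.07 and 1.75 and at 0.71 and 1.34.

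Of the 36 lists, camera called 10 higher and 2 lower, and with an estimated correlation 0 calls held, the lowest adjusted p being 0.353. With a score of erythroid, neutrophil and monocyte markers as a covariate, 6 of the 10 calls outside those markers stayed. The NK (0.20, adjusted p = 0.203), NF-kappaB (0.04, adjusted p = 0.156) and oncogene calls (0.06, adjusted p = 0.441) were lost with smaller medians, and the double-positive call (-0.08, adjusted p = 0.0693) with a median no nearer to 0. The values of the erythroid and monocyte lists in that fit are not read, since the score is made from them. The remaining lists did not pass with the choices used throughout. AP-1 and immediate early genes had a median log2 difference of 0.11 (adjusted p = 0.0539), with Ppp1r15a, a stress-induced phosphatase subunit, at 1.19 ± 0.23 (SE) and Junb, an AP-1 subunit, at 0.39 ± 0.09. The AP-1 list passed with cyclic loess (0.11, adjusted p = 0.0467), no normalization (0.05, adjusted p = 0.0439), the brighter probes (0.12, adjusted p = 0.0179) and genes above background alone (0.17, adjusted p = 0.0153), and without Klf4-deficient array 2 (0.11, adjusted p = 0.0255). Cholesterol and fatty acid synthesis genes had a median of 0.05 (adjusted p = 0.125), and Msmo1 passed when adjusted over the list alone (adjusted p = 0.00258). The cholesterol list passed without Klf4-deficient array 3 (0.11, adjusted p = 0.0063), with array weights (0.06, adjusted p = 0.0358) and with the marker score as a covariate (0.13, adjusted p = 0.00475), and its median was -0.02 with no normalization. The p53 targets had a median of 0.02 (adjusted p = 0.513), and among them Gadd45a passed when adjusted over the list alone (adjusted p = 0.0321), while the CDK inhibitor gene Cdkn1a, at 0.79 ± 0.17, did not. T cell receptor genes had a median of -0.06 (adjusted p = 0.513, and 0.0458 with the mean of a gene's probes, where it passed), and Lat, the adaptor that links the receptor to Ras and calcium signals, rose by 0.17 ± 0.03 when adjusted over the list alone (adjusted p = 0.0450). With the mean of its probes Lat differed by -0.15. Mature T cell genes had a median of 0.00 (adjusted p = 0.979), with the activation marker Cd69 at 0.85 ± 0.15. Notch pathway genes, the targets of the oncogene that induced the leukemia, had a median of 0.00 (adjusted p = 0.979), and Ncstn, a subunit of gamma-secretase, differed by -0.30 ± 0.08.

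The medians of glycolysis genes were 0.12 (adjusted p = 0.402 from camera), of oxidative phosphorylation genes -0.02 (adjusted p = 0.726) and of hypoxia genes -0.02 (adjusted p = 0.699). Anti-apoptotic genes had a median of 0.09 (adjusted p = 0.338) and pro-apoptotic genes one of 0.04 (adjusted p = 0.544). Other MAP kinase pathway genes had a median of 0.01 (adjusted p = 0.464), with the p38 kinase gene Mapk14 at 0.23 ± 0.05 (SE), and the Klf and Sp family one of 0.00 (adjusted p = 0.589). PI3K genes had a median of -0.07 with a mean of 0.02 (adjusted p = 0.190), and Tsc1 and Rptor, regulators of mTOR, differed by -0.32 ± 0.07 and -0.24 ± 0.05. CDK inhibitors had a median of -0.03 with a mean of 0.07 and a test pointing up (adjusted p = 0.867). JAK-STAT genes had a median of -0.01 with a mean of 0.03 and a test pointing up (adjusted p = 0.979). Chemokine receptors and adhesion genes had a median of 0.00 with a mean of 0.01 and a test pointing down (adjusted p = 0.909), and passed as lower with the marker score as a covariate (-0.08, adjusted p = 0.0430). The male-specific transcripts Eif2s3y and Kdm5d were above background on all 6 arrays. Xist, which is expressed from the inactive X chromosome of females, was above background on 0 of 3 control arrays and 3 of 3 Klf4-deficient arrays. Its signals were 11.6, 18.4 and 12 in the controls and 28.3, 26 and 23.3 in the Klf4-deficient arrays, groups that did not overlap, and it did not pass in limma (adjusted p = 0.530). The background limits of these Klf4-deficient arrays were close by, at 22.1, 22.1 and 21.8. The other Xist probes were under the limit on all 6 arrays.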

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

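The alternatives with no normalization, normalization before the floor, the first Klf4-deficient array alone, the marker score as a covariate, and genes above background alone were chosen after the data were seen. Over 22 alternatives the interferon list kept its direction, from 0.21 with the first Klf4-deficient array alone to 0.46. The histone list ran from -0.41 to -0.20, and Klf4 from 0.23 to 1.40 over 21 with 0 past the threshold. Leaving the lone-array fit aside, the interferon and histone lists lost the call only with the estimated correlation and with fry. All other alternatives keep the preset correlation of 0.01, so they cannot test it. The estimated correlations were 0.10 for the interferon and 0.43 for the histone list. Over all lists, 601 of 790 comparisons with an alternative kept sign and side of the threshold, 69 calls were lost and 25 gained with the sign kept. In 95, over 21 lists, the sign changed or the median was 0 in either fit, and 6 of these were past the threshold in either fit. Among the lists not called with the choices used throughout, the neutrophil list was past the threshold in 8 of 22 alternatives, 1 of them in the other direction, the megakaryocyte list in 7 of 21, the AP-1 list in 5 of 22, the G1/S and cholesterol lists in 3 each, and the G2/M, chemokine and T cell receptor lists in 1 each. The G1/S and G2/M lists each passed 1 time as higher, with the covariate. Over all named genes, 3265 of 3314 comparisons kept sign and side, 17 calls were lost, 13 were gained, and in 19, over 13 genes, the sign changed or the value was 0, with 0 of these past the threshold in limma. Genes near the background limit, where 8634 of the 19057 genes were not above it on any array, could not be read for direction. Fyb was called with only the brighter probes and with genes above background alone. Fewer genes are tested there (11452 and 8866 against 19057), but that is not the only change. The prior degrees of freedom, which set how strongly limma pools variances over genes, rose from 0.70 to 4.52 and 3.94. The cause was not tested for the changes below, except where the number of arrays or genes differs by construction.

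Genes higher numbered 1 with median-centred arrays, cyclic loess, offset 1, offset 50, no variance trend, robust moderation, the marker score as covariate and every probe tested, and 0 with the mean of probes. They numbered 34 at an unadjusted p under 0.01 with 1.5-fold, where 30 were lower, and 504 with the first Klf4-deficient array alone, where 7 were lower. In that fit the lone array is assumed to vary like the controls, so its counts of genes, lists and pathways are given but not read as differences. Genes lower numbered 1 with no normalization and 1, an unnamed probe, with every probe tested. Leaving out 1 array gave 1 to 21 genes higher and 0 to 9 lower. The replicate number as a block gave 0 genes higher and 1 Reactome pathway higher. In a check of pairing, the deviations of arrays with the same number correlated at 0.135, -0.041 and -0.066 across genes. Pairs with different numbers ran from -0.169 to 0.171. So few values cannot show whether the numbers mark a real pairing.

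Lists higher numbered 6 with median-centred arrays, 0 with an estimated correlation, 1 with fry and 3 with the first Klf4-deficient array alone. Lists lower numbered 1 with the brighter probes, 0 with an estimated correlation, 0 with fry and 0 with the first Klf4-deficient array alone, and leaving out 1 array gave 8 to 10 higher and 1 to 2 lower. Reactome pathways higher numbered 8 with median-centred arrays, 4 with the brighter probes, 8 with no normalization, 3 with the first Klf4-deficient array alone, 51 with the covariate and 8 with genes above background. Those lower numbered 51 with median-centred arrays, 46 with no normalization, 7 with the first Klf4-deficient array alone, 12 with the covariate, 0 with an estimated correlation and 0 with fry. Leaving out 1 array gave 0 to 50 higher and 19 to 41 lower.

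The JNK list's median was -0.036 with median-centred arrays, -0.061 with no normalization, -0.012 with the first Klf4-deficient array alone and -0.0096 with the covariate, and from -0.040 to 0.060 without 1 array. With the covariate the G1/S list lay at 0.078, the G2/M list at 0.17 and the neutrophil list at -0.40, and the neutrophil list is part of the score by construction. The Myc list lay at -0.021 with no normalization and from -0.0072 to 0.079 without 1 array. Mapk8 lay at -0.042 with median-centred arrays, -0.12 with the mean of probes and -0.067 with no normalization, and from -0.017 to 0.076 without 1 array. The planned result for Map2k7 was not run, since no probe carries its name. The variance trend and robust moderation do not enter camera, so they gave no values for lists or pathways.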

Other observations

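All tests in this part were chosen after the results were seen, except the counts over other splits of the arrays, and the genes of the next 2 paragraphs were chosen after their values were seen.

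The 4 genes Prg2, Epx, Ear3 and Ear6 had higher signal in every array labelled Klf4-deficient than in any control, although none passed in limma, and no list of such genes was fixed or tested. Prg2, which encodes the major basic protein of eosinophil granules, had a mean signal of 5498 in controls and 10813 in Klf4-deficient arrays (log2 1.11 ± 0.28 SE, adjusted p = 0.503). Epx, the eosinophil peroxidase gene, differed by 1.61 ± 0.38 (adjusted p = 0.489), and the eosinophil ribonuclease genes Ear3 and Ear6 by 1.42 ± 0.26 and 1.56 ± 0.37 (adjusted p = 0.420 and 0.480).

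Several other single genes are given as values, and none passed in limma. Nlrc5, the transactivator of MHC class I genes, differed by 1.41 ± 0.37 (SE, adjusted p = 0.515), and the class I gene H2-D1 by 0.72 ± 0.14 (adjusted p = 0.423). B2m, the common light chain of class I, differed by 0.04 ± 0.07 and H2-K1 by -0.30 ± 0.21. Fbln2, an extracellular matrix gene, had a mean signal of 946 in controls and 269 in Klf4-deficient arrays (log2 -1.62 ± 0.33, adjusted p = 0.426). Cirbp, a cold-induced RNA-binding protein, differed by -0.73 ± 0.16 (adjusted p = 0.449), and Tsc22d3, a glucocorticoid-induced gene also called Gilz, by 0.68 ± 0.08 (adjusted p = 0.327).

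Interferon-stimulated genes were higher in the 3 arrays labelled Klf4-deficient, with a median log2 difference of 0.34 for the fixed list and -0.04 for the Reactome pathway Interferon alpha beta signaling. RNA of erythroid, neutrophil and monocyte cells stays open as a cause. The group term of the list's median per array was 0.33 ± 0.07 (SE) alone and 0.25 ± 0.06 with the marker score as a covariate. With 6 arrays and a score that only approximates the amount of such RNA, this fit cannot exclude it. The score was 0.02, 0.57 and 1.54 in Klf4-deficient arrays 1, 2 and 3, the same order as the interferon list, and from -0.17 to 0.20 in the controls. The scaling of the arrays is argued against as the cause, since over 3 other normalizations and none the lowest median was 0.24. The real split of the arrays was the 1 of 10 with a median this large (0.34, highest other 0.22), and 10 splits are too few for a share under 0.05. Why the list and the Reactome pathway differ was not tested, and an effect of Klf4 deficiency, a difference between animals in exposure to interferon, and RNA of cells outside those 3 marker lists may each underlie the rise and were not tested.

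Erythroid, monocyte and NK markers were higher in the arrays labelled Klf4-deficient, mainly in arrays 2 and 3. A lower share of leukemia cells would raise the markers of all other cells alike only if those cells kept the same mix in every sample. The medians of erythroid, monocyte and neutrophil markers above background were 1.26, 0.80 and 0.45 over 14, 18 and 20 genes. A permutation of genes between the lists gave p = 1e-05, the smallest that 100000 resamples can give, and 2e-05 without genes over a signal of 10000. Genes of a list moved together, with estimated correlations of 0.52, 0.58 and 0.71, so they are not independent replicates. This p measures no spread between samples and cannot exclude a lower share of leukemia cells. Differing amounts of other cells' RNA in single samples cannot be told apart from a group effect: the erythroid list ranged over 1.57 within the Klf4-deficient arrays against a group difference of 0.91, but these values had been seen before the test was chosen, and sorting for GFP, CD4 and CD8 should remove such cells. The most abundant markers were strong on every array, with Hba-a1 signals of 33519 in controls and 38385 in Klf4-deficient arrays and S100a8 signals of 27430 and 24368, near the top of the scale. In Klf4-deficient array 3 the erythroid, neutrophil and monocyte lists lay at 1.75, 1.52 and 1.34, so a lower purity of that sample stays open. In Klf4-deficient array 2 they lay at 1.07, -0.08 and 0.71, which is not a uniform rise. Single cell types carried through the sort unequally and a change in the mix of marrow cells stay open too.

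The Klf4 probe was higher in the arrays labelled Klf4-deficient, at 1.03 ± 0.32 (SE). Spread of the background signal and between samples stays open: the mean signals differed by 41.7, which is 5.53 times the background SD of 7.53, but the control arrays already ran from 18.4 to 44, so that SD is no measure of the spread between samples. RNA of erythroid, neutrophil and monocyte cells cannot be told apart from a group effect, since the difference with the marker score as a covariate was 0.98 ± 0.46 and its spread is too wide. A probe that lies outside the deleted part of Klf4, which could leave a transcript that is still detected, and exchanged labels were not tested.

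The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes as the real 2 were called in 5 of the 10 splits (highest other 6), and as many lists as the real 12 in 1 of the 10 (highest other 11). As many Reactome pathways as the real 30 were called in 5 of the 10, and the highest other split called 161. The splits that placed control array 1 with Klf4-deficient array 3 called 152, 156, 138 and 161, and the others between 0 and 30. This points to a structure of the samples other than the groups. These 2 arrays were the lowest of the 6 for the G1/S list (-0.20 and -0.26) and the G2/M list (-0.22 and -0.28).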
